A study of Mus musculus with 35 samples.

How the data were processed

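The series holds 35 mouse samples: 25 RNA-seq libraries in 3 separate gene tables and 10 Ba/F3 chromatin samples, 9 of which have a peak list. Ba/F3 is a mouse pro-B cell line that grows on interleukin 3. Groups came from GEO's labels alone. The pre-B table holds 3 shPhf23.338, 4 shPhf23.877 and 3 shRen libraries, the lymphoma samples comprise 3 shPhf23.338 and 3 shRen libraries, and the drug samples comprise 3 libraries each for chidamide, entinostat and DMSO. shPhf23.338 and shPhf23.877 are hairpins against Phf23, and shRen is the control hairpin.

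Reads were aligned with STAR 2.6.0a to GRCm38, per the submitters' processing notes. The authors deposited whole-number counts per gene, with no normalization, and these counts entered every expression test. The counting tool, its strand setting and the library kit's strandedness were not given in the sources used here, so reads of overlapping, antisense and near-identical genes could not be told apart. The authors also deposited TPM values. These TPM columns summed to between 96965 and 172312 per library. Their ratio to counts-per-million (CPM) values was checked in genes well counted in every library of a table. These were 12400, 9808 and 10389 genes in the pre-B, lymphoma and drug tables. Within each of these genes the ratio was constant within 1%, so the TPM values were not used. The name table matched 51633 of 51912 gene IDs in each table. With the authors' own symbols filling gaps, 51692 IDs were named in the pre-B and lymphoma tables and 51683 in the drug table. IDs left unnamed held 0.0873%, 0.0363% and 0.0485% of counts in the pre-B, lymphoma and drug tables, and stayed in the tests.

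Peaks were called per sample with MACS2 2.1.1 on mm10, and deepTools was used, per the submitters' processing notes; the control and the calling threshold were not given in the sources used here. Per the file headers, which follow the MACS layout, each peak carries a score, a fold enrichment, a −log10 p and a −log10 q. These values, scores included, are the authors' and served only to rank or filter peaks within a list. The smallest −log10 q was 2.00.

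Expression was tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr on the groups, robust quasi-likelihood fits with a term per group, and Benjamini-Hochberg adjustment at 0.05. Each table was fitted once with all its groups, so that its groups shared an estimate of the spread. The pre-B effect of Phf23 hairpins was the mean of both hairpin groups minus shRen. CPM values use TMM library sizes within a table, and levels in different tables are not on a shared scale. DESeq2 1.42.0, RLE scaling, no low-count filter, a stricter filter (CPM of at least 5 in 3 libraries), only the compared groups in the fit, an absolute log2 fold change of 1 or more, the replicate number as a block, and each library left out were tried as alternatives fixed before the data were examined. Tests on RefSeq protein-coding genes alone and on peaks of at most 5 kb were added after the data were seen.

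The design, the tests, the 36 gene lists and the rule for naming genes were fixed at the same point. Lists with at least 3 measured members were tested with limma 3.58.1 camera on voom values (inter-gene correlation 0.01), adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. Members were counted as risen or fallen by edgeR over all genes, and with p-values adjusted over the list alone. Comparisons that share controls were set beside the overlap of independent lists and beside 20 simulations of unchanged groups. In these, all libraries were redrawn from the control means, controls included. Whatever is particular to the real control libraries is therefore not in them. The effect of shPhf23.338 in lymphoma was compared with that in pre-B cells by a limma interaction term over both tables.

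Every expression comparison names Phf23, Myc, Trp53, Hdac1 and Hdac2. It then names up to 8 higher and 8 lower genes by smallest p among those with an adjusted p under 0.05, an absolute log2 fold change of 1 or more (0.5 where fewer than 8 passed), a mean of at least 5 CPM in the higher group and non-overlapping CPM ranges, leaving out Gm, Rik, pseudogene and unnamed models. Up to 4 members with the smallest p were taken from each list described. For ChIP, the 10 shared Phf23 regions with the largest smaller-of-replicates −log10 q and the promoters of named genes were taken.

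Shared Phf23 regions are merged peaks of both replicates that overlap by at least 1 bp. Regions of H3K4me3, H3K27ac and Hdac1 are those found in at least 2 replicates. Shares have 95% Wilson intervals, which cover counting error only, and were set beside 100 random placements of the same regions on their own chromosomes. The input sample has no peak list in the files used here. No annotation at hand gave the strand of genes, so transcription start sites could not be placed as the design had foreseen. A gene was therefore called bound when a shared region lay within 1 kb of either gene end (2.5 kb as an alternative). Binding was tested against expression calls with a Mantel-Haenszel test over 10 deciles of mean expression, adjusted over the 20 tests run.

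For the comparisons that follow, the edgeR test was tried on simulated counts drawn from the real means and library sizes, with 200 genes changed. The peak overlap step was instead tried on 400 simulated intervals, and 0 differed from a direct comparison. For shPhf23.338 in pre-B cells, 92.5% of genes changed by 0.5 (log2) and 100% of those changed by 1 or 2 were recovered over 17137 genes. For chidamide, 86.6%, 100% and 100% were recovered over 13552 genes, and for shPhf23.877, 95.5%, 100% and 100% over 17134 genes. For the lymphoma knockdown, 7.46%, 77.6% and 98.5% were recovered over 13299 genes. Unchanged genes made up 5.80%, 7.73%, 6.19% and 10.3% of calls in the same order of comparisons. Other splits of the same libraries were refitted, up to 100 per comparison. Peak overlaps and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

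Replicate numbers in the labels did not pair the libraries by the rule set for it, so the comparisons in the report were fitted without them, and fits that use them are given as alternatives. No pair of libraries in a group agreed within sampling noise: over genes with at least 20 counts, chi-square per gene ran from 1.83 to 79.6. The labels do not say that pre-B or drug-treated replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.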

Results

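Expression was measured by polyA RNA-seq in mouse pre-B cells, in Myc-driven lymphoma and in lymphoma treated with histone deacetylase (HDAC) inhibitors, and chromatin binding by ChIP-seq in Ba/F3 cells. Pre-B cells were cultured with interleukin 7, infected with a retrovirus that carries a hairpin together with Myc and GFP, and sorted on GFP 48 h after infection. Lymphoma cells came from enlarged lymph nodes of recipient mice. Total counts per library were 22875284 to 27367885 in the pre-B table and 16542586 to 23456477 in the drug table. In the lymphoma table they were 16369228 to 20001387, except 41681864 in shRen replicate 3. The ChIP-seq data comprised 2 replicates each for FLAG-tagged Phf23, H3K4me3 and H3K27ac, 3 for Hdac1 and 1 input. Phf23 encodes a PHD finger protein, and its gene lies near Trp53 on mouse chromosome 11.

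Phf23 (ENSMUSG00000018572), the targeted gene, was lower in every library with a Phf23 hairpin than in every shRen library of the same table. In pre-B cells it was at 21.5, 21.7 and 22.4 counts-per-million (CPM) units with shPhf23.338, at 38.8, 40.7, 43.5 and 37.4 CPM with shPhf23.877, and at 46.6, 45.6 and 44.5 CPM with shRen. shPhf23.338 lowered it 2.09-fold (log2 fold change −1.06 ± 0.06, SE, adjusted p = 5.0e-10), whereas shPhf23.877 lowered it 1.14-fold (−0.19 ± 0.06, adjusted p = 0.016). The call for shPhf23.877 was lost without shPhf23.877 replicate 1 (−0.17), shPhf23.877 replicate 4 (−0.15) or shRen replicate 2 (−0.17). In lymphoma Phf23 was at 11.1, 12.2 and 15.5 CPM with shPhf23.338 against 44.5, 46.3 and 44.0 CPM with shRen, 3.47-fold lower (−1.80 ± 0.14, adjusted p = 0.0086). The drug-experiment libraries, whose labels name a Phf23 hairpin only for chidamide, held 17.9 to 21.6 CPM with DMSO, 12.4 to 13.0 CPM with chidamide and 12.8 to 15.5 CPM with entinostat.

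**Figure D1:**
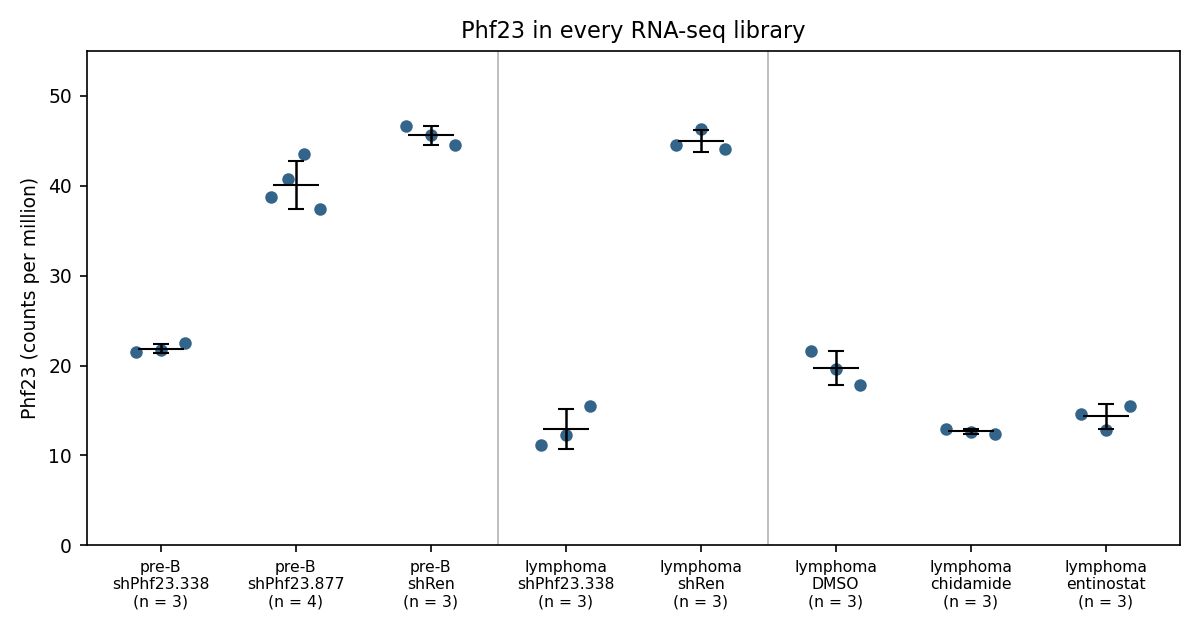
Phf23 in counts-per-million (CPM) units in each of the 25 libraries, by group, with group mean and SD; the 3 tables were scaled separately. Every library with a Phf23 hairpin lies below the shRen libraries of its table, and shPhf23.877 (37.4 to 43.5 CPM) lies closest to them.

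The first comparison asked what Phf23 knockdown changes in pre-B cells, taking the mean of both hairpins against shRen. Genes of myeloid cells were lower and genes of cholesterol synthesis were higher. MHC class II genes rose too, but as a list did not pass with an estimated correlation (adjusted p = 0.17). Mmp8, a neutrophil collagenase, fell from 26.0 ± 1.35 CPM (SD, n = 3) in shRen to 3.62 ± 0.586 CPM (n = 7), 7.17-fold. F13a1, a coagulation factor chain made by monocytes, fell from 18.2 ± 1.48 to 2.78 ± 0.349 CPM, 6.49-fold. Ccl22, a chemokine of activated dendritic and B cells, rose 2.62-fold from 3.59 ± 0.432 to 9.33 ± 0.717 CPM, and Fscn1, an actin-bundling protein, rose from 4.8 ± 0.866 to 12.4 ± 2.06 CPM.

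Beside these, the monocyte chemokine receptor Ccr2 (log2 fold change −2.28), Gpr141 (−2.47), Gda (−2.06), Chil3 (−1.76), Emilin2 (−1.74) and the imprinted noncoding RNA H19 (−1.97) were the genes lower by the naming rule. Apol7c (1.04), Acta2 (0.67), Bhlhe41 (0.52), the lymph node homing receptor Ccr7 (0.51), Dtx1 (0.51) and Emid1 (0.51) were those higher. Myc (ENSMUSG00000022346) rose by 0.43 ± 0.04 (SE, adjusted p = 1.1e-06), from 970.7 ± 21.4 (SD, n = 3) to 1327 ± 123 CPM (n = 7). This measure may include reads from the vector's own Myc, which the counts cannot set apart. Trp53 (0.14, adjusted p = 0.052, passed in 8 of 17 alternatives), Hdac1 (−0.04, adjusted p = 0.61) and Hdac2 (−0.05, adjusted p = 0.46) did not pass the test.

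Of 8 measured granulocyte markers, 8 fell (8 adjusted over the list alone), with Ltf at −2.48 and Ngp at −2.26, 2 proteins of neutrophil granules (camera adjusted p = 3.6e-14, adjusted p = 0.040 with an estimated correlation). Of 11 macrophage and monocyte markers, 6 fell and 5 did neither (7 fell adjusted over the list alone), among them the lysozyme gene Lyz2 (−1.99), the receptor for colony-stimulating factor Csf1r (−1.51) and Fcgr1 (−2.25, camera adjusted p = 7.7e-07, adjusted p = 0.046 with an estimated correlation). Summed over the macrophage list, shRen libraries held 137.6, 146.2 and 107.1 CPM, shPhf23.338 libraries 39.3 to 46.5 CPM and shPhf23.877 libraries 42.4 to 50.9 CPM. For the granulocyte list these sums were 40 to 52.0 CPM, 18.3 to 23.2 CPM and 11.7 to 17.2 CPM. Of 4 dendritic cell markers, 1 fell and 3 did neither (1 fell adjusted over the list alone, camera adjusted p = 0.21). Ccl22, Fscn1, Ccr7 and Apol7c are not in that list. Whether their rise lies in the pre-B cells or in other cells of the cultures was not tested.

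Of 21 cholesterol synthesis genes, 18 rose, 0 fell and 3 did neither (20 rose adjusted over the list alone, camera adjusted p = 2.6e-16, adjusted p = 0.040 with an estimated correlation). The enzymes Cyp51 (0.37), Fdft1 (0.44), Hmgcs1 (0.34) and Sqle (0.34) had the smallest p-values. Of 10 MHC class II genes, 8 rose and 2 did neither (8 adjusted over the list alone, camera adjusted p = 1.4e-07, adjusted p = 0.17 with an estimated correlation), including the chains H2-Eb1 (0.47) and H2-Aa (0.45), the invariant chain Cd74 (0.45) and the peptide-loading subunit H2-DMb2 (0.49). Of 32 B cell maturation genes, 15 rose and 17 did neither (18 rose adjusted over the list alone, camera adjusted p = 2.0e-06, adjusted p = 0.13 with an estimated correlation), among them the inhibitory receptor Cd22 (0.28) and the kinase Blk (0.26).

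Of 27 Myc target ribosome biogenesis genes, 12 rose and 15 did neither (15 rose and 1 fell adjusted over the list alone), with Bop1 at 0.28 and Nop16 at 0.27 (camera adjusted p = 2.2e-05, adjusted p = 0.19 with an estimated correlation). Of 21 G2/M genes, 8 fell, 2 rose and 11 did neither (10 fell and 3 rose adjusted over the list alone), with the mitotic genes Cenpf at −0.26 and Tpx2 at −0.18 (camera adjusted p = 0.015, adjusted p = 0.17 with an estimated correlation). p53 target genes passed neither way as a list: of 19, 3 rose, 1 fell and 15 did neither (7 and 2 adjusted over the list alone, camera adjusted p = 0.17). Of 28 SIN3 and NuRD deacetylase complex genes, 6 rose and 22 did neither (8 rose adjusted over the list alone, camera adjusted p = 0.20).

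By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1314 of 17418 genes were higher and 1203 lower. At 2-fold or more these were 30 and 211 genes. The count of 2517 fell to 1545 without shRen replicate 3 and to 1468 without shRen replicate 4.

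**Figure D2:**
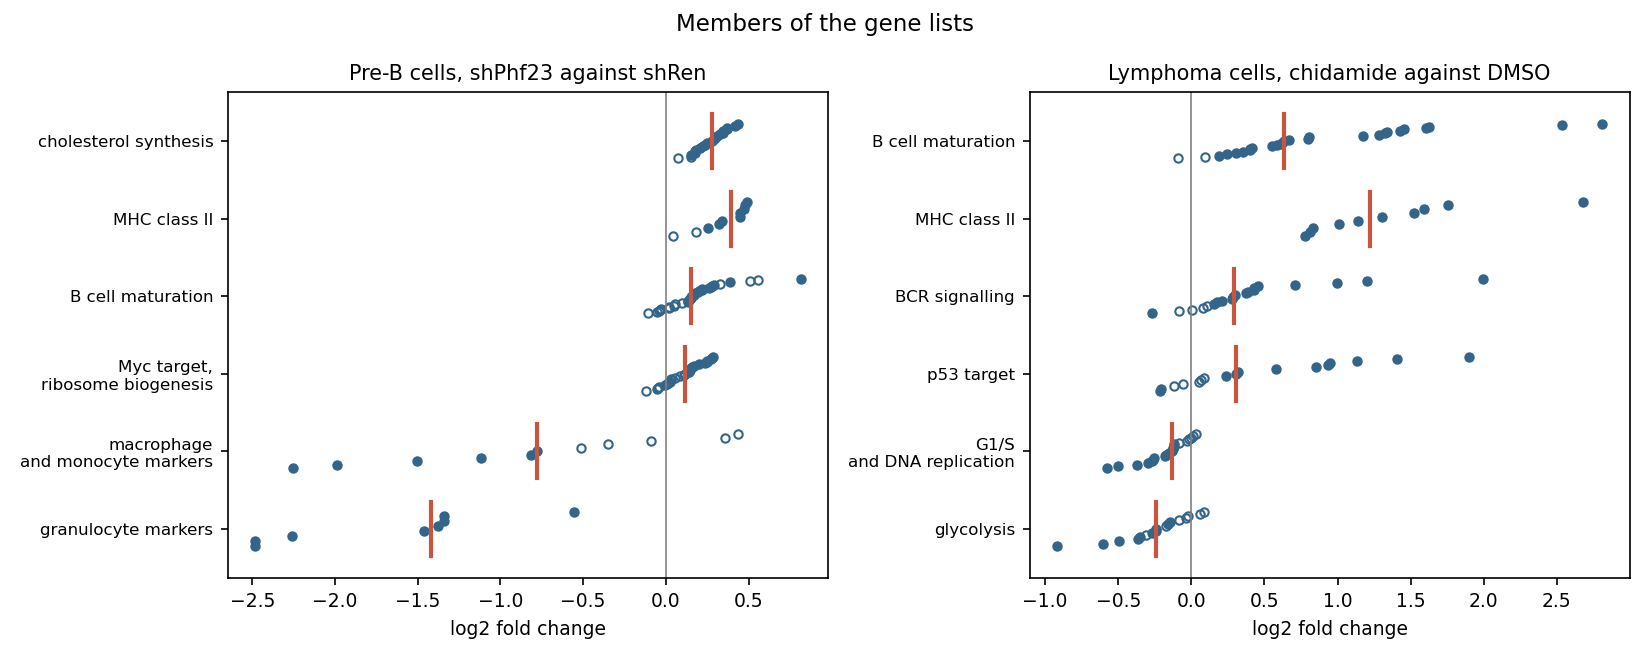
Log2 fold changes of the measured members of 6 gene lists for the mean of both Phf23 hairpins against shRen in pre-B cells, and of 6 for chidamide against DMSO in lymphoma; filled points have an adjusted p under 0.05 over all genes, and red bars mark medians. The 8 granulocyte markers are all filled and below 0 in pre-B cells (median −1.42), and the 10 MHC class II genes are all filled and above 0 with chidamide (median 1.22).

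Taken alone against shRen, shPhf23.338 gave the following values for these groups. Ccl22 was 2.70-fold higher, Cyp51 rose from 107.2 ± 1.69 (SD, n = 3) to 154.5 ± 11.5 CPM (n = 3; log2 fold change 0.53 ± 0.05, SE, adjusted p = 1.4e-06), and Fscn1 (1.49), Apol7c (1.2), Bhlhe41 (0.58), Ccr7 (0.55), Rasgrp3 (0.52) and Adarb1 (0.50) were also higher. Mmp8 (−2.87), Gpr141 (−2.66), F13a1 (−2.56), Ccr2 (−2.28), Emilin2 (−1.99), Gda (−1.95) and the haemoglobin-binding protein Hp (−1.53) were lower. Of 21 cholesterol synthesis genes, 14 rose and 7 did neither (20 rose adjusted over the list alone, camera adjusted p = 1.4e-20, adjusted p = 0.023 with an estimated correlation). Of 26 autophagy and lysosome genes, 7 fell and 19 did neither (11 fell adjusted over the list alone, camera adjusted p = 4.3e-06, adjusted p = 0.035 with an estimated correlation), led by the cathepsins Ctsl (−0.83), Ctsd (−0.32) and Ctsz (−0.28) and by Lamp2 (−0.27). Of the 8 granulocyte markers 6 fell and 2 did neither (8 fell adjusted over the list alone, camera adjusted p = 2.7e-13, adjusted p = 0.032 with an estimated correlation), and of the 11 macrophage markers 6 fell and 5 did neither (7 fell adjusted over the list alone, camera adjusted p = 7.7e-08, adjusted p = 0.032 with an estimated correlation).

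Myc rose by 0.31 with shPhf23.338 (adjusted p = 0.00060). Trp53 (0.09, adjusted p = 0.42), Hdac1 (−0.01, adjusted p = 0.93) and Hdac2 (0.07, adjusted p = 0.48) did not pass. In all, 368 genes were higher and 515 lower with shPhf23.338, 26 and 184 of them at 2-fold or more. The count of 883 fell to 500 without shPhf23.338 replicate 2 and to 523 without shRen replicate 3, and to 541 with only the compared groups in the fit, 573 under the stricter filter.

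shPhf23.877, which lowered Phf23 least, changed more genes than shPhf23.338: 2478 were higher and 2245 lower, 77 and 333 of them at 2-fold or more. H2-Eb1 rose from 69.3 ± 4.77 (SD, n = 3) to 107.4 ± 6.74 CPM (n = 4), the smooth muscle actin gene Acta2 from 8.66 to 17.2 CPM (log2 fold change 0.99 ± 0.08, SE), the ribosomal protein gene Rpl18 by 0.57, Neil1 by 0.70, Gnas by 0.55 and Laptm5 by 0.51. H19 was 6.63-fold lower (−2.73 ± 0.12), Lyz1 4.03-fold lower and the adhesion protein gene Emb 2.20-fold lower, with F13a1 (−2.84), Mmp8 (−2.81), Ccr2 (−2.27), Gda (−2.17) and Chil3 (−2.06). Of 10 MHC class II genes, 8 rose and 2 did neither (9 rose adjusted over the list alone), with the class II transactivator Ciita at 0.39 (camera adjusted p = 7.3e-08, adjusted p = 0.19 with an estimated correlation). Of 21 G2/M genes, 13 fell, 3 rose and 5 did neither (14 fell and 4 rose adjusted over the list alone), with the proliferation marker Mki67 at −0.29 and Tpx2 at −0.34 (camera adjusted p = 0.00054, adjusted p = 0.078 with an estimated correlation). Of 8 granulocyte markers 8 fell (8 adjusted over the list alone, camera adjusted p = 1.4e-09, adjusted p = 0.078 with an estimated correlation), of 11 macrophage markers 6 fell and 5 did neither (6 fell adjusted over the list alone, camera adjusted p = 1.0e-04, adjusted p = 0.11 with an estimated correlation), and of 21 cholesterol synthesis genes 17 rose and 4 did neither (18 rose adjusted over the list alone, camera adjusted p = 4.5e-09, adjusted p = 0.078 with an estimated correlation). Of 34 lists, 16 passed camera for shPhf23.877 and 0 with an estimated correlation.

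Myc rose by 0.55 ± 0.05 with shPhf23.877 (adjusted p = 8.8e-08) and Trp53 by 0.19 (adjusted p = 0.0087; not passed without shRen replicate 4), Hdac2 fell by 0.18 (adjusted p = 0.0097), and Hdac1 (−0.07, adjusted p = 0.36) did not pass. Of 13 mitochondrially encoded genes, 6 fell and 7 did neither (9 fell adjusted over the list alone, camera adjusted p = 1.0e-04, adjusted p = 0.36 with an estimated correlation). These genes took 5.14% to 5.39% of counts in shPhf23.877 libraries, 5.90% to 6.49% in shRen and 6.20% to 6.71% in shPhf23.338.

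The fold changes of both hairpins correlated across genes at Pearson r = 0.54. Unchanged groups sharing simulated controls, all drawn from the shRen means, gave a mean of 0.54 (highest 0.56 of 20). Genes are not independent replicates. The covariance was 0.0602 against a simulated 0.0160, a difference of 0.0442. The share of genes with the same sign was 64.8%, below the simulated mean of 68.1% (highest 68.9%). The simulations shared 0 calls in either direction, but they hold no changed genes, so this was fixed in advance and is no measure for the overlap. Both hairpins raised 205 genes and lowered 348, where independent lists would share 52.3 and 66.4, and 16 genes went in opposite directions. With 3 shRen libraries the controls could not be split, so part of the excess may come from the shared controls.

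Set directly against each other, shPhf23.338 and shPhf23.877 differed in 3968 genes, 1922 higher and 2046 lower with shPhf23.338. Mt-Nd2, a subunit of respiratory complex I, was at 3703 ± 249 CPM (SD, n = 3) with shPhf23.338 and 2250 ± 119 CPM (n = 4) with shPhf23.877. The nucleosome-binding protein gene Hmgn5 (0.70 ± 0.06, SE), Zcchc10 (0.74), Skp2 (0.58), Ppig (0.57), Cd36 (0.55), Srpr (0.54) and H19 (1.51) were higher with shPhf23.338, and Wdr34 (−0.84), Nme4 (−0.70), Wdr90 (−0.69), Acta2 (−0.65), Wdr81 (−0.63), Spns1 (−0.60) and Ypel3 (−0.59) were lower. Phf23 itself was lower with shPhf23.338 (−0.87 ± 0.06, adjusted p = 2.7e-09), as was Myc (−0.23, adjusted p = 0.0016), while Hdac2 was higher (0.26, adjusted p = 0.00098) and Trp53 (−0.11, adjusted p = 0.15) and Hdac1 (0.05, adjusted p = 0.49) did not pass. Of 13 mitochondrially encoded genes, 10 were higher and 3 neither (11 adjusted over the list alone, camera adjusted p = 1.6e-08, adjusted p = 0.38 with an estimated correlation). Of 10 MHC class II genes, 5 were lower and 5 neither (10 lower adjusted over the list alone, camera adjusted p = 0.00014, adjusted p = 0.50 with an estimated correlation). Of 21 G2/M genes, 11 were higher, 1 lower and 9 neither (11 and 2 adjusted over the list alone, camera adjusted p = 0.00042, adjusted p = 0.16 with an estimated correlation). Without shPhf23.338 replicate 3 the count was 2549.

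In lymphoma the comparison asked what shPhf23.338 changes in established tumours. Only Phf23 was called lower and only Elovl6 (ENSMUSG00000041220), a fatty acid elongase, higher among 13628 genes by edgeR. Elovl6 was at 79.2 ± 8.0 CPM (SD, n = 3) with shPhf23.338 and 36.1 ± 2.27 CPM (n = 3) with shRen, 2.20-fold higher (log2 fold change 1.14 ± 0.11, SE, adjusted p = 0.026). Myc was at 1823 ± 491 CPM against 833.3 ± 44.0 CPM (1.13, adjusted p = 0.12, passed in 3 of 12 alternatives), and Trp53 (0.09, adjusted p = 0.63), Hdac1 (0.11, adjusted p = 0.60) and Hdac2 (0.16, adjusted p = 0.42) did not pass.

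No member of a list passed over all genes; 16 of 36 lists passed camera and 0 passed with an estimated correlation. Members of the Myc target ribosome biogenesis list had a median of 0.27 (0 of 27 passed, 2 rose adjusted over the list alone, camera adjusted p = 2.3e-09, adjusted p = 0.61 with an estimated correlation), with Srm at 0.44 and Cad at 0.45. NF-kB target genes had a median of −1.03 (0 of 12 passed, 7 fell adjusted over the list alone, camera adjusted p = 5.7e-05, adjusted p = 0.61 with an estimated correlation), with Nfkb2 at −1.33. Interferon-stimulated genes had a median of −0.63 (0 of 24, 3 fell adjusted over the list alone, camera adjusted p = 5.7e-05, adjusted p = 0.61 with an estimated correlation), with the GTPase gene Gbp2 at −2.48. T cell markers had a median of −1.57 (0 of 16, 0 adjusted over the list alone, camera adjusted p = 5.7e-05, adjusted p = 0.61 with an estimated correlation), and their summed level was 86.4, 42.2 and 29.3 CPM with shPhf23.338 and 248.7, 42.9 and 162.2 CPM in shRen replicates 1, 2 and 3. Dendritic cell markers had a median of −1.45 (0 of 9, 4 fell adjusted over the list alone, camera adjusted p = 0.00041, adjusted p = 0.61 with an estimated correlation), at 5.24 to 10.1 CPM against 14.6 to 37.1 CPM in sum. Stromal and endothelial markers summed to 73.8 to 86.4 CPM with shPhf23.338 and 69.0 to 84.3 CPM with shRen. The samples came from lymph nodes. For the lists that fell, a change in tumour cells therefore cannot be told apart from a smaller share of other cells.

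The 2 calls stood against 2101 genes at an unadjusted p under 0.05 and 483 calls by DESeq2 (174 higher). The count was 0 without shPhf23.338 replicate 2 or shRen replicate 3, 3 without shPhf23.338 replicate 1, 11 without shRen replicate 2 and 13 without shPhf23.338 replicate 3; Elovl6 also lost its call without shPhf23.338 replicate 1 or shRen replicate 1. Mitochondrially encoded genes took 13.7%, 11.3% and 7.56% of counts in shRen replicates 1, 2 and 3 and 12.6% to 12.9% with shPhf23.338, and their list had a median of 0.28 (0 of 13 passed, 0 adjusted over the list alone, camera adjusted p = 0.0059, adjusted p = 0.67 with an estimated correlation).

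Across the 13120 genes tested in both tables, the fold changes of the pre-B and lymphoma knockdowns had a Spearman correlation of 0.16 (0.26 for shPhf23.338 alone), across genes that are not independent. The single gene lower in both was Phf23 (0.0694 with independent lists; Fisher's exact p = 0.069, 2-sided), and 0 genes were higher in both.

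The drug comparisons asked what HDAC inhibition for 12 h changes in lymphoma cells. Both compounds are benzamide HDAC inhibitors. Chidamide has a fluorine on its aminoanilide ring and a pyridyl acrylamide linker where entinostat has a pyridylmethyl carbamate. Doses were not given in the sources used here. The chidamide libraries alone carry a Phf23 hairpin in their labels. By the labels, a hairpin effect and a drug effect cannot be separated for them. Their Phf23 level was 12.7 CPM, against 14.3 CPM with entinostat (log2 difference −0.18 ± 0.095, SE). In the lymphoma knockdown, shPhf23.338 changed Phf23 by −1.80 ± 0.14. For Phf23, these values argue against a hairpin of that strength in the chidamide libraries alone. A weaker hairpin effect stays open, as does a hairpin present in all drug groups.

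With chidamide, genes of mature B cells and of antigen presentation were among those that rose. Cd74 (ENSMUSG00000024610), the MHC class II invariant chain, rose 3.01-fold from 127.1 ± 6.50 (SD, n = 3) to 383.2 ± 13.1 CPM (n = 3; log2 fold change 1.59 ± 0.05, SE, adjusted p = 6.8e-18). Cd37, a tetraspanin of mature B cells, rose from 77.3 ± 5.12 to 195.6 ± 3.05 CPM, Gvin1, an interferon-inducible GTPase, 5.75-fold, Sema4g 3.98-fold and Pld4 3.48-fold. Sp100 (1.42), Tmsb4x (1.46) and Cd53 (1.26) were also higher. Tubb3, a neuronal beta-tubulin, fell 3.08-fold from 70.6 ± 3.54 to 22.9 ± 1.45 CPM, and Prom1 fell 3.42-fold from 7.19 to 2.1 CPM, with Ntn1 (−1.41), Adra2c (−1.37), Smoc1 (−1.29), Lrfn4 (−1.15), Frmpd1 (−1.13) and Rbm24 (−1.07).

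Of 27 B cell maturation genes, 24 rose, 0 fell and 3 did neither (25 and 1 adjusted over the list alone), with Ms4a1, which encodes CD20, at 2.54 and S1pr1 at 1.29 (camera adjusted p = 2.4e-17, adjusted p = 0.0019 with an estimated correlation). Of 10 MHC class II genes, 10 rose (10 adjusted over the list alone), with H2-Eb1 at 1.31 (camera adjusted p = 1.4e-10, adjusted p = 0.036 with an estimated correlation). Of 20 BCR signalling genes, 15 rose, 1 fell and 4 did neither (15 and 1 adjusted over the list alone), with the scaffold Card11 at 1.2 and the phosphatase Ptpn6 at 1.00 (camera adjusted p = 4.7e-07, adjusted p = 0.036 with an estimated correlation). Of 17 p53 target genes, 10 rose, 2 fell and 5 did neither (10 and 2 adjusted over the list alone), with the cell cycle inhibitor Cdkn1a at 1.90 and Trp53inp1 at 1.4 (camera adjusted p = 0.00032, adjusted p = 0.046 with an estimated correlation). In all, 21 of 32 lists passed camera with chidamide and 5 with an estimated correlation.

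Lists of other B cell stages and of other cell types rose with chidamide as well, by camera but not with an estimated correlation. Of 19 early B and pre-BCR genes, 12 rose, 3 fell and 4 did neither (12 and 3 adjusted over the list alone), with Rag1 at 1.02 and Il7r at −0.79 (camera adjusted p = 0.0053, adjusted p = 0.18 with an estimated correlation). Of 8 stromal and endothelial markers, 4 rose and 4 did neither (4 adjusted over the list alone), with a median of 0.44 (camera adjusted p = 0.0067, adjusted p = 0.18 with an estimated correlation). Of 5 macrophage and monocyte markers, 3 rose and 2 did neither (3 adjusted over the list alone), with a median of 1.05 (camera adjusted p = 0.033, adjusted p = 0.18 with an estimated correlation).

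Of 21 G1/S and DNA replication genes, 14 fell and 7 did neither with chidamide (14 adjusted over the list alone), with Gins2 at −0.58 and Tyms at −0.50 (camera adjusted p = 0.00028, adjusted p = 0.036 with an estimated correlation). Of 17 glycolysis genes, 10 fell and 7 did neither (10 adjusted over the list alone), with Pfkl at −0.92 and the hexokinase gene Hk2 at −0.60 (camera adjusted p = 9.1e-05, adjusted p = 0.18 with an estimated correlation). Of 28 SIN3 and NuRD deacetylase complex genes, 13 fell, 2 rose and 13 did neither (14 and 2 adjusted over the list alone), with Mbd3 at −0.53 and Sin3a at −0.40 (camera adjusted p = 0.0031, adjusted p = 0.058 with an estimated correlation). Of 8 genes often induced by HDAC inhibitors, 4 rose, 2 fell and 2 did neither (4 and 3 adjusted over the list alone, camera adjusted p = 0.26). Tubb3, a member of this list, was at −1.62, Txnip at 1.14 and H1f0 at 0.56. Hdac2 fell by 0.33 ± 0.05 (SE, adjusted p = 6.3e-06) and Phf23 by 0.64 ± 0.09 (adjusted p = 5.0e-06), while Hdac1 (0.09, adjusted p = 0.19), Myc (0.08, adjusted p = 0.27) and Trp53 (−0.05, adjusted p = 0.35) did not pass.

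Entinostat, whose libraries carry no hairpin label, also raised B cell and antigen presentation genes. Cd74 was 2.48-fold higher (315.0 ± 14.8 CPM; SD, n = 3), Sla, an adaptor that dampens antigen receptor signalling, rose 3.26-fold from 12.2 ± 1.18 to 39.7 ± 1.65 CPM, and S1pr1 rose from 43.7 ± 1.4 to 99.1 ± 2.53 CPM. Sema4g (1.69), Pld4 (1.59), Tmsb4x (1.25), Cd37 (1.18) and Cd53 (1.12) were higher too. Tubb3 fell 2.53-fold, and Pfkl, the liver-type phosphofructokinase, fell from 95.2 ± 6.57 to 54.7 ± 2.34 CPM, with Rbm24 (−0.91), Podxl (−0.79), Marcksl1 (−0.71), Nt5dc2 (−0.64), Pkp4 (−0.58) and Fabp5 (−0.58). Of 27 B cell maturation genes, 25 rose and 2 did neither (25 adjusted over the list alone, camera adjusted p = 3.5e-20, adjusted p = 0.0012 with an estimated correlation). Of 10 MHC class II genes, 10 rose (10 adjusted over the list alone, camera adjusted p = 5.8e-11, adjusted p = 0.037 with an estimated correlation), and of 20 BCR signalling genes, 14 rose, 1 fell and 5 did neither (14 and 1 adjusted over the list alone, camera adjusted p = 4.5e-07, adjusted p = 0.044 with an estimated correlation).

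Of 19 early B and pre-BCR genes, 10 rose, 4 fell and 5 did neither with entinostat (11 and 5 adjusted over the list alone, camera adjusted p = 0.0077, adjusted p = 0.19 with an estimated correlation), and of 8 stromal and endothelial markers 3 rose and 5 did neither (3 adjusted over the list alone, camera adjusted p = 0.017, adjusted p = 0.24 with an estimated correlation). Of 5 macrophage and monocyte markers 2 rose, 1 fell and 2 did neither (3 and 1 adjusted over the list alone, camera adjusted p = 0.32). Of 17 p53 target genes, 9 rose, 1 fell and 7 did neither with entinostat (9 and 2 adjusted over the list alone), with Cdkn1a at 1.55 (camera adjusted p = 0.00025, adjusted p = 0.051 with an estimated correlation). Of 17 glycolysis genes, 10 fell and 7 did neither (10 adjusted over the list alone, camera adjusted p = 2.7e-05, adjusted p = 0.19 with an estimated correlation). Of 21 G1/S and DNA replication genes, 6 fell and 15 did neither (6 adjusted over the list alone, camera adjusted p = 0.028, adjusted p = 0.14 with an estimated correlation). Of the 28 deacetylase complex genes, 12 fell, 3 rose and 13 did neither (13 and 3 adjusted over the list alone, camera adjusted p = 0.0040, adjusted p = 0.067 with an estimated correlation). Hdac2 fell by 0.24 (adjusted p = 0.00047) and Phf23 by 0.46 ± 0.09 (SE, adjusted p = 0.00038), while Hdac1 (0.06, adjusted p = 0.42), Myc (0.05, adjusted p = 0.50) and Trp53 (0.00) did not pass.

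By edgeR, 2779 genes were higher and 2703 lower with chidamide among 14000, and 2126 and 2009 with entinostat. At 2-fold or more the counts were 561 and 52 with chidamide and 349 and 45 with entinostat. Fold changes of both drugs correlated across genes at Pearson r = 0.89. Unchanged groups sharing simulated controls, all drawn from the DMSO means, gave a mean of 0.51 (highest 0.53). The covariance was 0.166 against a simulated 0.0162, a difference of 0.15. The share of genes with the same sign was 85.7% against a simulated mean of 67.0%. The simulations averaged 0.15 and 0.05 shared calls, but they hold no changed genes, so this was fixed in advance and is no measure for the overlap. Both drugs raised 1952 genes and lowered 1778, where independent lists would share 422.0 and 387.9, and 0 genes called for both went in opposite directions. The 3 DMSO libraries could not be split, so part of the excess may come from the shared controls.

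**Figure D3:**
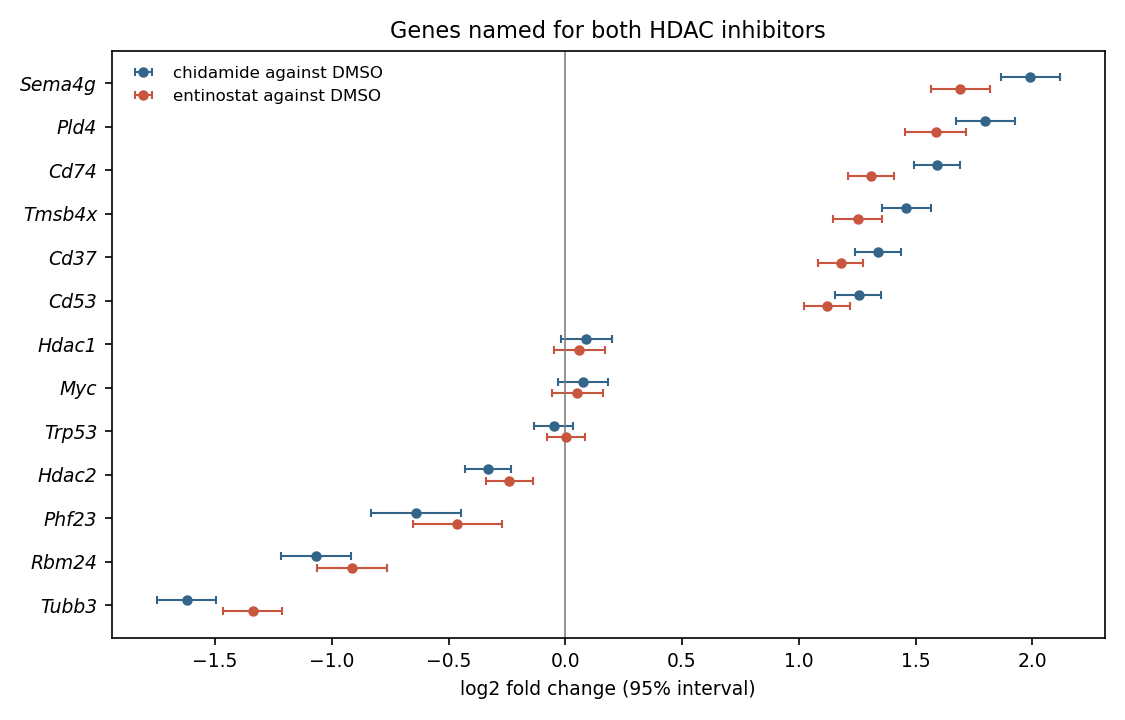
Log2 fold change against DMSO with 95% intervals for the 13 genes named for both chidamide and entinostat (3 libraries a group, 12 h). Cd74 stands at 1.59 with chidamide and 1.31 with entinostat, and Tubb3 at −1.62 and −1.34.

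Tested directly by edgeR, chidamide and entinostat differed in 7 genes, all higher with chidamide, a direction that some other fits, given below, did not keep. Hip1 (ENSMUSG00000039959), a clathrin adaptor gene, was at 20.5 ± 0.0826 CPM (SD, n = 3) with chidamide and 14.3 ± 1.89 CPM (n = 3) with entinostat (log2 difference 0.52, 95% interval 0.32 to 0.71, adjusted p = 0.038). Cd74 (0.28, adjusted p = 0.034) and the early B cell surface protein gene Cd93 (0.41, adjusted p = 0.038) also passed. Differences for Phf23 (−0.18, 95% interval −0.37 to 0.02), Hdac2 (−0.09, −0.19 to 0.01), Hdac1 (0.03, −0.08 to 0.14), Myc (0.02, −0.08 to 0.13) and Trp53 (−0.05, −0.13 to 0.03) did not pass, and the intervals leave room for differences of that size. As lists, MHC class II genes were higher with chidamide (1 of 10 passed, 7 adjusted over the list alone, camera adjusted p = 5.3e-08, adjusted p = 0.0496 with an estimated correlation), with a median of 0.23. B cell maturation genes were higher (0 of 27 passed, 5 adjusted over the list alone, camera adjusted p = 0.00021, adjusted p = 0.0496 with an estimated correlation), with a median of 0.06, and G1/S and DNA replication genes lower (0 of 21 passed, 0 adjusted over the list alone, camera adjusted p = 6.2e-06, adjusted p = 0.0496 with an estimated correlation), with a median of −0.06. Macrophage and monocyte markers were higher (0 of 5 passed, 1 adjusted over the list alone, camera adjusted p = 0.0054, adjusted p = 0.16 with an estimated correlation), with a median of 0.32. The MHC class II, B cell maturation and G1/S lists moved the same way with both drugs against DMSO. Across all genes, the slope of entinostat on chidamide fold changes was 0.77. With unknown doses, a larger response to chidamide cannot be told apart from a response of another kind.

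This count of 7 compares with 1467 genes at an unadjusted p under 0.05 and 17 calls by DESeq2, of which 5 were higher and 12 lower with chidamide and 1 was among the 7. It was 0 without chidamide replicate 1, 2 or 3 or entinostat replicate 2 and 59 (29 higher, 30 lower) without entinostat replicate 3. It was 96 (64 higher, 32 lower) with no low-count filter, 40 (29 higher, 11 lower) among protein-coding genes and 1 under the stricter filter. With the replicate block or with only the compared groups in the fit it was 0, and no called gene differed 2-fold.

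The design pairs the knockdown with HDAC inhibition, which allowed asking whether they move genes the same way in lymphoma. Across 12690 genes, fold changes of the lymphoma knockdown and of the drugs had Spearman correlations of −0.19 for chidamide and −0.13 for entinostat. Elovl6, higher with the hairpin, was lower with both drugs (Fisher's exact p = 0.21 and 0.15, 2-sided), and Phf23 was lower with all 3, so that with 2 knockdown calls the overlap could not be tested further.

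In Ba/F3 cells that express FLAG-tagged mouse Phf23, the ChIP comparison asked where Phf23 sits relative to active chromatin marks and to Hdac1 (mm10 coordinates). The replicates held 8510 and 5912 Phf23 peaks with median widths of 1479 and 1452 bp. They shared 4419 regions, with 55.4% of replicate 1 and 84.8% of replicate 2 peaks overlapping the other list. Of the shared regions, 91.2% (95% Wilson interval 90.4% to 92.0%) overlapped H3K4me3, the mark of active promoters, against at most 5.52% of 100 random placements. H3K27ac, a mark of active promoters and enhancers, overlapped 68.0% (66.6% to 69.4%; random at most 4.68%). Hdac1 overlapped 8.98% (8.18% to 9.86%; random at most 2.85%), or 397 regions. Both histone marks were present at 63.9% of regions, H3K4me3 alone at 27.4%, H3K27ac alone at 4.12% and neither at 4.64%.

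Peak width mattered for Hdac1: 39.98%, 21.7% and 29.2% of peaks in its 3 lists were wider than 5 kb, against 8.61% and 9.19% for Phf23. With peaks of at most 5 kb, an alternative chosen after the data were seen, the overlap with Hdac1 was 1.78%, or 69 regions (random at most 0.155%), and those with H3K4me3 and H3K27ac 80.9% and 58.9%. With any replicate in place of shared regions the Hdac1 share was 20.2%, with −log10 q of at least 5 it was 5.17%, without Hdac1 replicate 2 it was 5.05% and without Phf23 replicate 1 it was 14.5%.

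**Figure D4:**
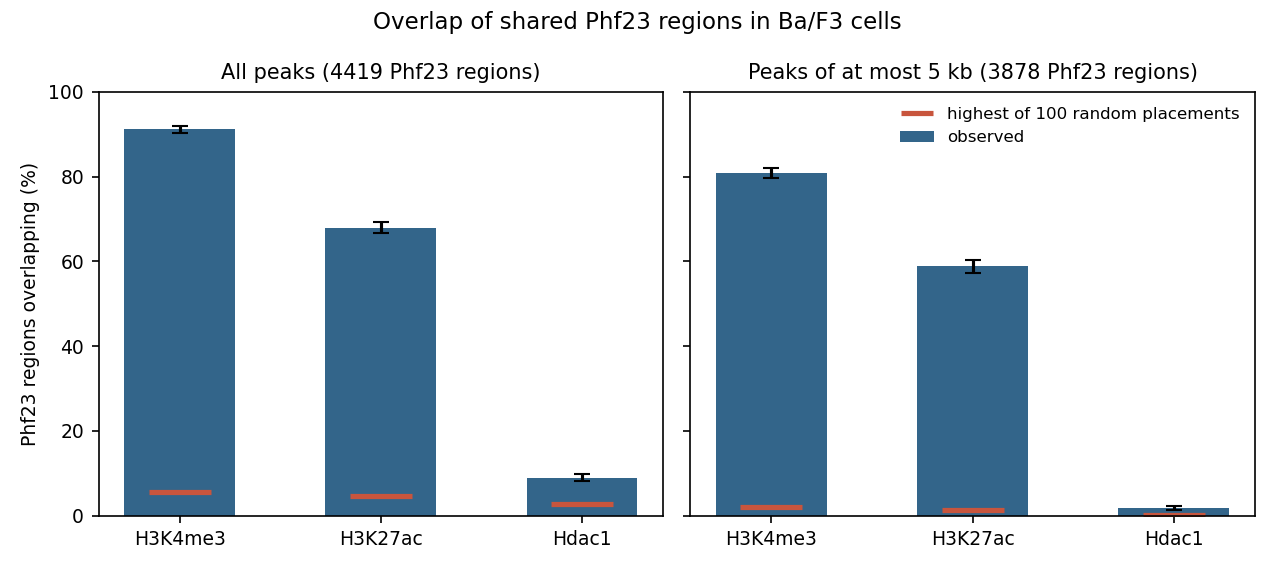
Percent of shared Phf23 regions in Ba/F3 cells that overlap H3K4me3, H3K27ac or Hdac1 regions, with 95% Wilson intervals, for all peaks (4419 regions) and for peaks of at most 5 kb (3878 regions); markers give the highest of 100 random placements. H3K4me3 stands at 91.2% and 80.9%, Hdac1 at 8.98% and 1.78%.

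The 10 shared Phf23 regions with the largest −log10 q were all wider than 100 kb and lay in all 3 other sets of regions. Of 104 merged Phf23 regions over 100 kb, 60 overlapped a peak over 100 kb of each other antibody. Such wide peaks covered 40.3 of 64.6 Mb in Phf23 replicate 1 and 36.8 of 54.9 Mb in replicate 2. A high rank therefore does not mark a site as particular to Phf23. The top region was on chromosome 4, 145406116 to 147586212 (−log10 q 456.2), and held an end of 72 genes, mostly zinc finger and predicted genes; that on chromosome 12, 21638178 to 24379370, held 40. Among peaks of at most 5 kb, chosen after their values were seen, the top region lay between Cdca5 and Zfpl1 on chromosome 19, 6083951 to 6086005 (−log10 q 79.6). Another lay at Uhrf1 on chromosome 17, 56301926 to 56306125 (70.2), and of these 10 regions 9 overlapped H3K4me3, 7 H3K27ac and 0 Hdac1.

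Of 70 named genes with coordinates, 18 had a Phf23 region, 27 an H3K4me3 region, 20 an H3K27ac region and 3 an Hdac1 region at a gene end. Of all genes tested, 4633 of 15999 in the pre-B table and 4364 of 13063 in the drug table had a Phf23 region. Named genes thus had such a region no more often than tested genes at large. Phf23 itself (chromosome 11, 69995766 to 70000011; −log10 q 30.1) and Myc (chromosome 15, 61985341 to 61990361; −log10 q 15.3) had a Phf23 region with both histone marks. Wdr34 (48.1), Srpr (41.8), Pfkl (40.05), Hip1 (18.9), Rpl18, Cd37, Tubb3 and Podxl also had a Phf23 region, and Ccr2, Srpr and Gvin1 had both Phf23 and Hdac1. Binding was measured with tagged, added Phf23, in another cell type than the expression.

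Genes with a Phf23 region at either end were set against expression calls within deciles of expression. This test treats genes as independent, and by camera none of the associations in this paragraph passed after adjustment. With shPhf23.877, 20.2% of Phf23-bound genes were higher against 12.7% of others, a Mantel-Haenszel odds ratio of 1.30 (95% interval 1.18 to 1.42, adjusted p = 1.9e-06), and the odds of being lower were 0.783 (0.704 to 0.872, adjusted p = 1.0e-04). For the mean of both hairpins these odds ratios were 1.16 (1.02 to 1.31, adjusted p = 0.053) and 0.804 (0.696 to 0.928, adjusted p = 0.012). With shPhf23.338, the stronger knockdown, neither direction passed (higher 0.782, 0.619 to 0.987, adjusted p = 0.088; lower 1.13, adjusted p = 0.37). With chidamide, 25.4% of bound genes were lower against 17.8% (odds ratio 1.22, 1.11 to 1.34, adjusted p = 2.0e-04), and with entinostat 18.7% against 13.5% (1.198, 1.08 to 1.33, adjusted p = 0.0028), with odds of being higher of 0.882 (adjusted p = 0.022) and 0.859 (adjusted p = 0.013).

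Among Hdac1-bound genes, those lower with shPhf23.877 were more frequent (1.36, 1.09 to 1.70, adjusted p = 0.019), and this ratio was 0.723 with peaks of at most 5 kb. No other Hdac1 test passed with all peaks and a 1 kb window. With peaks of at most 5 kb, Hdac1-bound genes were more often lower with chidamide (odds ratio 1.75, 95% interval 1.18 to 2.59, unadjusted p = 0.0061) and entinostat (1.73, 1.14 to 2.62, unadjusted p = 0.014), and less often higher with chidamide (0.567, unadjusted p = 0.042). The test treats genes as independent, and by camera, which allows for correlation between genes, no association with all peaks passed (adjusted p from 0.271 to 0.963 for the sets named). With peaks of at most 5 kb, camera gave unadjusted p = 0.0099 for lower values of Hdac1-bound genes with chidamide and 0.048 with entinostat, 0.049 for lower values of Phf23-bound genes with chidamide and 0.035 for higher values with shPhf23.877. The lymphoma knockdown had too few calls for this test.

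**Figure D5:**
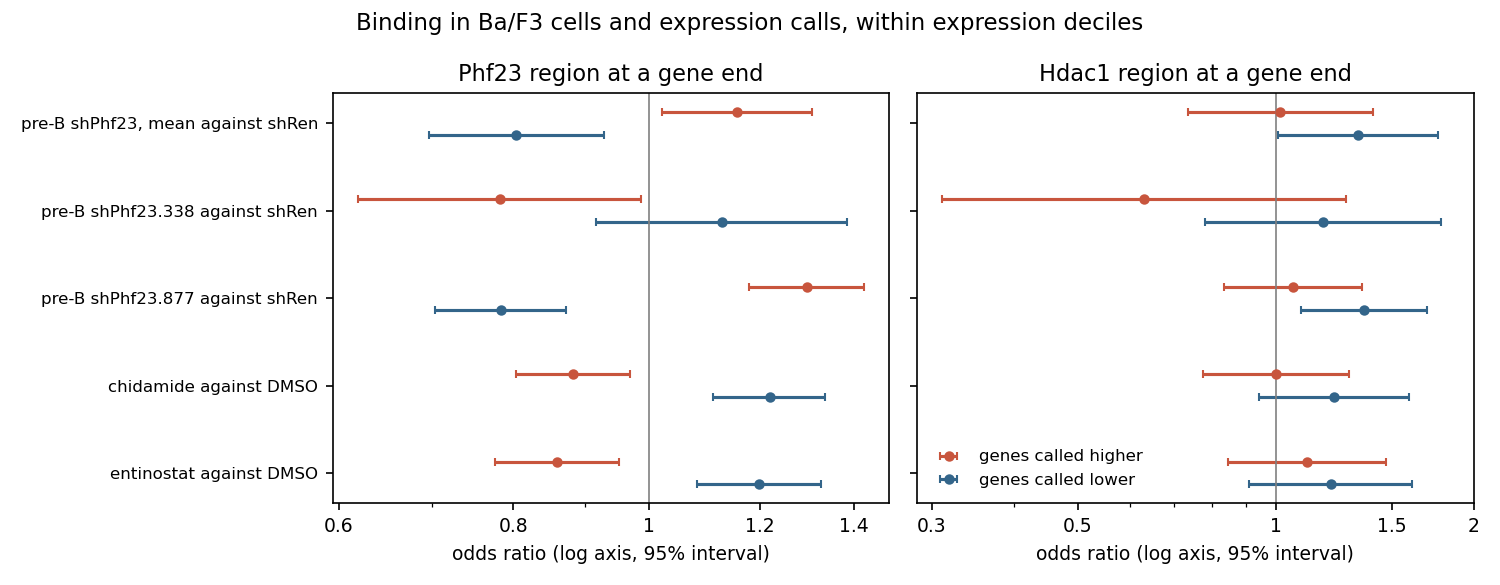
Mantel-Haenszel odds ratios with 95% intervals, on a log axis, for genes with a Phf23 or Hdac1 region within 1 kb of a gene end to be called higher or lower in each comparison, stratified by expression decile. Phf23-bound genes lie above 1 for being higher with shPhf23.877 (1.30) and for being lower with chidamide (1.22).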

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

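The tests of an odd control library and of fewer myeloid cells were chosen only after the result was seen; the splits were planned. In pre-B cells, Gpr141, a receptor gene of myeloid cells, was at 0.7785 CPM in shPhf23.877 replicate 2, far below the other 3 libraries of its group (group mean 1.2 CPM; gap 0.860 of the range, where 0.829 is the critical value). Of 44 values checked in groups of 4, 1 stood apart in this way, and chance alone gives about 1 in 20.

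The effect of shPhf23.338 was compared between lymphoma and pre-B cells for 26 named genes with a limma interaction term, and 2 differed. F13a1 had a log2 fold change of −2.56 in pre-B cells and −0.29 in lymphoma, an interaction estimate of 2.20 (adjusted p = 0.040). Elovl6 had 0.12 in pre-B cells and 1.14 in lymphoma, an interaction estimate of 1.02 (adjusted p = 0.0057). Over 17939 genes, 17 differed at an adjusted p under 0.05 and 1872 at an unadjusted p under 0.05. Phf23 (adjusted p = 0.11) and Mmp8 (adjusted p = 0.13) did not pass. Among genes of opposite sign were Ccl22 (1.43 in pre-B cells, −1.12 in lymphoma), Fscn1 (1.49, −1.57) and Apol7c (1.2, −1.36). Their interaction terms did not pass (adjusted p = 0.24, 0.19 and 0.23).

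F13a1, Mmp8 and Ccr2 were lower with each hairpin in pre-B cells. With shPhf23.338 and shPhf23.877 their log2 fold changes were −2.56 and −2.84, −2.87 and −2.81, and −2.28 and −2.27. Phf23 itself fell 2.09-fold and 1.14-fold, so the size of these falls did not follow that of Phf23. The granulocyte and macrophage lists were lower for the mean of both hairpins and for shPhf23.338, also with an estimated correlation, while for shPhf23.877 they passed camera but not with an estimated correlation (adjusted p = 0.078 and 0.11). A single odd shRen library was argued against: the median over the 19 list members was −1.34, and its value nearest 0 with a shRen library left out was −1.11, without replicate 2. A trait common to all shRen libraries, which both hairpins were compared with, cannot be seen in this way and stays open. Fewer myeloid cells in the hairpin cultures stay open. A loss of one kind of cell lowers all its markers by a like fold, and 6 of the 19 members (31.6%) had the median in their 95% interval, but other cells may express some members, so this uneven fall decides nothing. Of the 19 members 14 were called lower. The cells had been sorted on GFP, which would remove uninfected myeloid cells but not infected ones. A lower level of these transcripts in each cell after Phf23 knockdown stays open and was not tested.

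Other splits of the libraries were refitted with only the compared groups. For shPhf23.877 against shRen, 1 of 35 splits gave as many calls (the real one, 4701 calls, highest other 0). For shPhf23.338 against shPhf23.877 it was also 1 of 35 (4595 calls, highest other 4). That share is under 0.05, but it is the smallest that 35 splits can give. A culture difference between the groups would give it too, so it does not show that the hairpins are the cause. For both hairpins together, the splits set the 7 hairpin libraries, pooled as 1 group, against the 3 of shRen, another model than the mean of 2 hairpin groups, which gave 2517 calls. There, 2 of 100 drawn splits gave at least the real 701 calls; the other, with 800 calls, set shPhf23.877 replicates 1, 2 and 3 against the other 7 libraries, a structure in which shPhf23.877 stands apart from both shPhf23.338 and shRen. The 10 splits of 3 against 3 are too few for a share under 0.05. Their real and highest other counts were 541 and 3 for shPhf23.338 against shRen, 2 and 1 for the lymphoma knockdown, 5890 and 0 for chidamide and 3866 and 0 for entinostat, each reached by 1 of 10 splits. For chidamide against entinostat they were 0 and 1, reached by 10 of 10.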

How the results depend on the processing

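Scaling by RLE left all 8 expression counts within 1.5 times their value. Alternatives chosen after the data were seen were those on protein-coding genes and on peaks of at most 5 kb. Across settings, 165 results stayed, 34 lost and 14 gained a call or a count, 23 moved and 1 reversed; where no cause is given, the cause was not tested. No named gene reversed. Calls lost in some setting were Phf23 and Trp53 for shPhf23.877, Phf23 and Elovl6 in lymphoma and Hip1 between the drugs. Calls gained were Trp53 for the mean of both hairpins in 8 of 17 alternatives (log2 fold change 0.14 by DESeq2, 0.18 without shRen replicate 3), Myc in lymphoma in 3 of 12 (1.12 with no low-count filter, 1.15 by DESeq2, 1.28 without shPhf23.338 replicate 3), Myc with entinostat without entinostat replicate 3 (0.11) and Trp53 between the hairpins with the replicate block (−0.13).

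Requiring a 2-fold change, which leaves fewer genes by construction, gave 241 calls for the mean of both hairpins, 210 for shPhf23.338, 410 for shPhf23.877, 288 for shPhf23.338 against shPhf23.877, 613 for chidamide, 394 for entinostat and 0 between the drugs (7 without it). For shPhf23.338 against shRen, the stricter filter gave 573 calls and a fit of only the compared groups 541. In lymphoma (2 calls) no low-count filter gave 272 and DESeq2 483. Between the drugs (7 calls, all higher with chidamide) no low-count filter gave 96 calls (32 lower), the stricter filter 1, DESeq2 17 (12 lower), protein-coding genes 40 (11 lower) and only the compared groups 0. With each library left out in turn, counts ran from 1468 (without shRen replicate 4) to 2961 for the mean of both hairpins, 500 to 1249 for shPhf23.338, 2549 to 3325 for shPhf23.338 against shPhf23.877, 0 to 13 in lymphoma and 0 to 59 between the drugs, with fewer samples in each fit.

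The replicate numbers did not pair the libraries: the lowest correlation of same-numbered libraries was −0.0368 in pre-B cells, 0.0687 in lymphoma and −0.18 in the drug table. With the replicate block there were 4 calls in lymphoma, 0 between the drugs, 2702 for the mean of both hairpins, 1002 for shPhf23.338, 5246 for shPhf23.877, 4814 for shPhf23.338 against shPhf23.877, 5333 for chidamide and 4023 for entinostat. Another label numbers the pre-B shRen libraries from 1, and its replicate block gave 2943, 1086, 4799 and 3790 for the 4 pre-B comparisons.

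Of 268 list tests, 121 passed camera, 18 of these with an estimated correlation, 114 passed fry for change on balance one way and 196 for change in either direction. Of the 121, 84 passed the one-way fry test and 37 did not, among them the 16 in lymphoma. Simulated covariances were 0.0160 for the hairpins and 0.0162 for the drugs. The Spearman correlation of pre-B and lymphoma knockdowns was 0.26 with shPhf23.338 alone.

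The share of Phf23 regions on H3K4me3 was 94.8% at −log10 q of at least 5, 81.9% for any replicate and 80.9% for peaks of at most 5 kb, and ran from 73.9% (without Phf23 replicate 2) to 95.6% (without H3K4me3 replicate 1). For H3K27ac these were 65.1%, 74.7% and 58.9%, from 51.3% (without Phf23 replicate 2) to 85.9% (without H3K27ac replicate 2). For Hdac1 they were 5.17%, 20.2% and 1.78%, from 5.05% (without Hdac1 replicate 2) to 14.5% (without Phf23 replicate 1).

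For binding against expression, tests without expression strata gave an odds ratio of 1.64 for Phf23-bound genes higher by the mean of both hairpins (gained), and 0.924 and 0.981 for those higher with chidamide and entinostat (lost). In simulated calls that rose with expression, with a true odds ratio of 1, tests without strata averaged 1.235 and those with strata 0.997. Ratios without strata can therefore lie above 1 through expression alone. With peaks of at most 5 kb the ratio was 0.713 for Phf23-bound genes higher with shPhf23.338 (gained), 0.723 for Hdac1-bound genes lower with shPhf23.877 (reversed, no longer passed), and 1.75 and 1.73 for Hdac1-bound genes lower with chidamide and entinostat (gained). By ranks (camera), the calls made with all peaks were lost: adjusted p = 0.296 for Phf23 and the mean of both hairpins, 0.271 for Phf23 and 0.963 for Hdac1 with shPhf23.877, 0.313 with chidamide and 0.578 with entinostat. With peaks of at most 5 kb, ranks gave unadjusted p = 0.0099 for lower values of Hdac1-bound genes with chidamide and 0.048 with entinostat, 0.049 for lower values of Phf23-bound genes with chidamide and 0.035 for higher values with shPhf23.877.

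The coefficient of biological variation between libraries was 0.248 in lymphoma, 0.0583 in pre-B cells and 0.0533 in the drug table. How far depth, rather than this spread, limits the lymphoma comparison was not tested.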

Other observations

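Tests of group size, pseudogene reads and wide peaks, and the overlaps of pre-B and drug calls, were chosen only after the result was seen. The rule for the test of open promoters was written before its value was seen. That test used peaks of at most 5 kb, a filter chosen after the data were seen. Values of further lists for the mean of both hairpins in pre-B cells follow, and none of these lists passed with an estimated correlation. Of 16 amino acid and integrated stress response genes, 8 rose, 1 fell and 7 did neither (9 and 1 adjusted over the list alone), with the asparagine synthetase gene Asns at 0.31 and the transcription factor gene Cebpb at −1.18 (camera adjusted p = 6.8e-05, adjusted p = 0.17 with an estimated correlation). Of 23 neighbours of Phf23 and Trp53 on chromosome 11, 6 rose and 17 did neither (9 rose adjusted over the list alone), with Wrap53 at 0.26 (camera adjusted p = 0.00032, adjusted p = 0.17 with an estimated correlation). Of 24 early B and pre-BCR genes, 5 rose, 4 fell and 15 did neither (5 and 4 adjusted over the list alone), with the receptor gene Flt3 at 0.90 and terminal transferase Dntt at −0.58 (camera adjusted p = 0.33). Of 15 NF-kB target genes, 4 rose and 11 did neither (4 adjusted over the list alone), with Bcl3 at 0.50 (camera adjusted p = 0.013, adjusted p = 0.44 with an estimated correlation).

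In lymphoma, MHC class I presentation genes had a median of −0.37 (0 of 15 passed, 1 fell adjusted over the list alone, camera adjusted p = 5.7e-05, adjusted p = 0.61 with an estimated correlation), with H2-Q4 at −1.02. Granulocyte markers had a median of −0.90 (0 of 8 passed, 5 fell adjusted over the list alone, camera adjusted p = 7.6e-05, adjusted p = 0.61 with an estimated correlation). For these lymphoma lists too, a change in tumour cells cannot be told apart from a smaller share of other cells. With chidamide, 12 of 15 stress response genes rose and 2 fell (12 and 2 adjusted over the list alone, camera adjusted p = 0.00028, adjusted p = 0.18 with an estimated correlation), and of 10 pro-apoptotic Bcl2 family genes 3 rose, 1 fell and 6 did neither (3 and 1 adjusted over the list alone, camera adjusted p = 0.21), with Bmf at 1.70 and Pmaip1 at 0.95. Of 13100 genes tested in pre-B cells and with drugs, 354 were higher by the mean of both hairpins and lower with chidamide, against 221.5 with independent lists (Fisher's exact p = 4.8e-23, 2-sided, as in the sentences that follow), 174 lower and higher, against 156.9 (p = 0.12), 238 higher in both, against 215.9 (p = 0.081), and 131 lower in both, against 160.9 (p = 0.0062). For shPhf23.338 and chidamide, 98 were higher and lower, against 58.7 (Fisher's exact p = 4.7e-08), 100 lower and higher, against 65.7 (p = 5.1e-06), 69 higher in both, against 57.2 (p = 0.086), and 33 lower in both, against 67.4 (p = 3.7e-07). For the mean of both hairpins and entinostat, 240 were higher and lower, against 163.8 (Fisher's exact p = 1.5e-10), 142 lower and higher, against 121.7 (p = 0.042), 218 higher in both, against 167.4 (p = 1.7e-05), and 118 lower in both, against 119.1 (p = 0.96). For shPhf23.338 and entinostat, 67 were higher and lower, against 43.4 (Fisher's exact p = 0.00022), 90 lower and higher, against 51.0 (p = 2.8e-08), 70 higher in both, against 44.4 (p = 6.6e-05), and 38 lower in both, against 49.9 (p = 0.073). Genes are not independent, and these tests, unlike the binding tests, were not stratified by expression. For shPhf23.338 and entinostat, pairs higher in both and pairs in opposite directions all exceeded independent lists. An excess in these counts therefore does not by itself show opposing effects. Spearman correlations with chidamide were −0.05 for the mean of both hairpins and −0.08 for shPhf23.338, and with entinostat −0.02 and −0.05.

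More genes were called for shPhf23.877 than for shPhf23.338 although Phf23 fell less with shPhf23.877. The larger group of 4 libraries was argued against as the whole cause, since the lowest count for shPhf23.877 with 3 libraries was 3806, against 883 for shPhf23.338. Calls on genes other than protein-coding ones were argued against as the whole cause. Among protein-coding genes alone, shPhf23.877 still had 3.53 times the calls of shPhf23.338 (3685 and 1044). Reads shared with pseudogenes can shift counts of protein-coding genes too, so this test cannot exclude shared reads. In the main fit, 28.8% of protein-coding and 23.65% of other genes were called for shPhf23.877. For shPhf23.338 these shares were 6.51% and 2.13%. Off-target effects of either hairpin may contribute and were not tested, and a culture difference between these groups cannot be excluded because the labels name no batches.

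Phf23 regions overlapped Hdac1 regions in 8.98% of cases. Very wide peaks present in every list were argued against as the whole cause: with peaks of at most 5 kb the share was 1.78%, above the highest of 100 random placements (0.155%), although it fell from 8.98%. Open promoters that attract all 4 antibodies cannot be told apart from a specific overlap. In peaks of at most 5 kb, Hdac1-overlapping regions lay on H3K4me3 in 73.9% of 69 cases and other regions in 81.0%, which is 91.3% of their share. The rule, written before this value was seen but for a peak filter chosen after the data were seen, read 90% or more as open promoters. The interval of 77.2% to 102.2%, considered after the value was seen, spans that bound and keeps the question open.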
